A study of Drosophila melanogaster with 6 samples.

How the data were processed

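Total RNA from 6 samples, pools of fly heads per the labels, was labelled with biotin and hybridised to Affymetrix Drosophila Genome 2 arrays, after amplification of 150 ng per sample, per the labels. There were 3 pools from flies aged 10 days and 3 from flies aged 40 days, described as independent biological replicates. The deposited values are on a log2 scale, as their range and their lowest value of 2.06 show. Per the submitters' processing notes they were made with GCRMA, which corrects background, normalizes between arrays and summarises the probes of a probe set. The version of GCRMA, the annotation build and any filters are not given in the sources used here. Raw scans, detection calls and scan dates were not used here. The table held no control probe sets, and each array had a value for all 15131 probe sets.

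Probe sets were assigned to genes through the gene names given for the array: 13333 had 1 gene, 390 several and 1408 none. The RefSeq gene table of the assembly Release 6 plus ISO1 MT was used for names and for the order of neighbouring genes. Probe sets with a mean log2 value of at least 4 over the 6 arrays were tested, 10286 in all. The values were used as deposited, without further normalization.

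The 40-day and 10-day samples were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided. P values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, at the level of 8846 genes, each represented by its brightest probe set, and adjusted over the lists tested. Of 34 lists, 31 had at least 5 measured members. The lists of Turandot stress peptides, of ovary and egg genes, and of odorant, gustatory and ionotropic receptors had fewer and were not tested. Members were also adjusted over the list alone. Marker levels are the mean over the 6 arrays of the brightest probe set of each gene, dim ones included. Tables and plots were made with Python, pandas 2.3.3 and matplotlib 3.10.9.

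Genes were named by a rule. Among probe sets past the threshold, with 1 gene and with no overlap between the ages, the 10 largest rises and the 10 largest falls are named. For each list described, up to 4 members with the smallest adjusted p are named, and for lists of other tissues and of males up to 4 members with the highest mean. For a gene with several probe sets the values are those of the probe set that met the rule, and a brighter one of the same gene is given beside it. Names outside this rule were chosen after their values were seen: *Arr2* and *Arr1* for their level, *Cyp4d21* as a P450 gene called with the block, the yolk protein genes, and the neighbouring and list genes of the closing observations. The test between the ages, the list tests, the lists, the naming rule and the alternatives were chosen before the data were examined, except for the fits without both samples of number 2 and the fit with both a block and an estimated correlation. The tests of the explanations weighed in the closing observations were chosen later.

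The replicate numbers come from the labels, which do not say that they pair samples across ages. After the age means were removed, samples with the same number correlated at 0.707, 0.772 and 0.353 for numbers 1, 2 and 3, all above the threshold of 0.1, and all 6 samples correlated best with the sample of their own number. The numbers were therefore taken to pair the samples. The planned fit without a block is reported first, and values with the number as a block are given where a call or a count differs.

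The test was also run on simulated data with 3 samples per group and 100 changed probe sets at each size. It recovered 92% of changes at a log2 difference of 1 and 99% at 2, with 10 false calls among 201. The real data gave 35 calls, and more calls loosen the adjusted threshold, so recovery in the real data may be lower. A simulated list of 30 genes shifted by 0.5 log2 was recovered, and 0 of 20 lists without a shift were called. Simulated values varied independently, without correlation between genes or differences between replicate numbers. The simulation therefore does not show how often lists of correlated genes are called wrongly, nor recovery at smaller shifts. Alternatives were no filter on dim probe sets, a filter at 6, median centring, quantile normalization, eBayes without a trend or robust, a replicate block, array weights, a plain t statistic, values floored at 4, each sample left out in turn, an estimated correlation, fry, and the mean of all probe sets of a gene.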

Results

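RNA from 6 *Drosophila melanogaster* samples was measured on Affymetrix 3' expression arrays. The labels describe all 6 samples as pools of heads of female flies of the Canton S laboratory strain, with 3 pools from flies aged 10 days and 3 from flies aged 40 days. A pool held 75 to 100 heads, per the labels. The comparison asks which transcripts differ between younger and older adult flies. Expression values were reported for 15131 probe sets, and the 10286 with a mean log2 value of at least 4 were tested. The 6 arrays had medians between 7.51 and 7.53, and between 2774 and 2809 probe sets per array lay at the lowest value of the table, 2.06. Correlations between arrays, taken across the tested probe sets, ranged from 0.974 to 0.992. The number of arrays limits the precision of each value.

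Transcripts of the male reproductive tract were among the brightest in all 6 samples labelled female heads. The male-specific list, which holds accessory gland and testis genes, had a median log2 level of 14.04 over 26 genes, and 22 of them lay in the top 10% of probe sets. The seminal fluid protein genes *Acp53Ea*, *Acp98AB*, *Mst57Da* and *Acp36DE* reached 15.45 ± 0.20, 15.40 ± 0.10, 15.38 ± 0.10 and 14.84 ± 0.37 (mean log2 ± SD, n = 6). Digestive enzymes of the gut had a median of 11.25 over 37 genes, with *alphaTry*, *Jon65Aiv*, *betaTry* and *Jon65Aiii*, which encode secreted proteases, between 14.89 and 15.21. Ovary and egg genes lay at the floor, with a median of 2.06 over 26 genes and 22 of them under 4. The brightest ovary gene was *exu* at 12.79 ± 0.17, a gene that also acts in spermatogenesis. On single arrays the median of the male-specific list ran from 13.90 to 14.27, and that of the ovary list stayed at 2.06. These levels go against the female head label of the samples, so the ages below are those of samples labelled female heads.

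**Figure D1:**
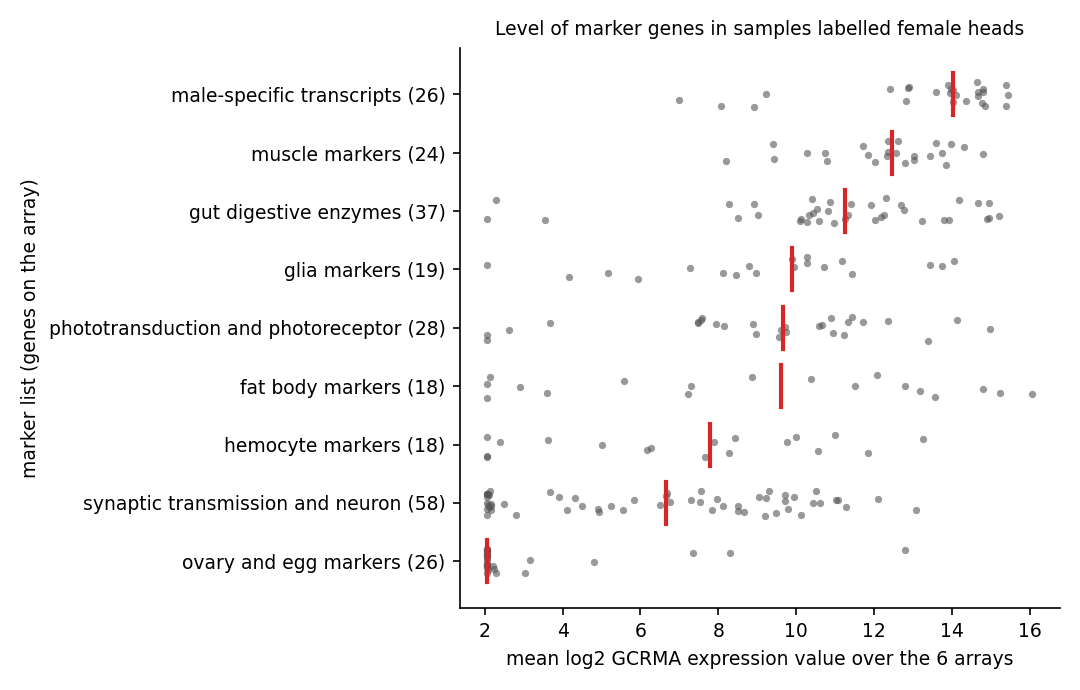
Levels of marker genes in the 6 samples labelled female heads. The x axis gives the mean log2 GCRMA expression value over the 6 arrays, each grey point is 1 gene of the list named on the y axis, and the red bar is the median of the list. The male-specific list has a median of 14.04, against 2.06 for ovary and egg genes.

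Photoreceptor, neuronal and glia genes were present beside them, as were markers of fat body, muscle and hemocytes, tissues not confined to the head. Phototransduction and photoreceptor genes had a median of 9.67 over 28 genes, and the arrestin genes *Arr2* and *Arr1*, which end the light response, reached 14.97 ± 0.07 and 14.14 ± 0.12 (n = 6). Synaptic and neuronal genes had a median of 6.67 over 58 genes, 19 of them under 4. Glia markers had a median of 9.91 over 19 genes. Fat body markers had a median of 9.62 over 18 genes, with *Cyp4g1*, *apolpp*, *FASN1* and *Tsf1* between 13.56 and 16.07. Muscle markers had a median of 12.46 over 24 genes, led by *Mf* at 14.79 ± 0.07, and hemocyte markers one of 7.78 over 18 genes, led by *SPARC* at 13.25 ± 0.10. No test was run between the levels of different genes.

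The ages and the replicate numbers both separated the samples. Differences between the ages made up 29.8% of the spread over the tested probe sets, differences between the replicate numbers 58.3%, and the rest 11.8%. There were more replicate numbers than ages, so these shares do not rank the sources. The first principal component, with 45.6% of the spread, set both samples of replicate number 2 apart, at 26.8 and 20.1, from the other samples, which lay between -21.5 and -2.13. The second, with 29.9%, parted the ages: the 10-day samples lay between -16.9 and -11.6 and the 40-day samples between 13.2 and 15.1. Without both samples of number 2, the share between the ages was 48.9%, a share that also rises by chance with fewer samples.

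Few probe sets passed the test between the ages without the replicate block, and most of those moved at least 2-fold. Of 10286 probe sets, 35 differed between 40 and 10 days by limma with Benjamini-Hochberg adjustment, 17 higher and 18 lower at 40 days. They stand for 31 single genes, 2 probe sets with no gene name and 1 with several. A change of at least 2-fold was seen for 28 of them, 15 higher and 13 lower. At any p, 105 of the tested probe sets differed by at least 2-fold. With the replicate number as a block, limma called 198 probe sets, 64 higher and 134 lower, which held all 35, and 62 of at least 2-fold. At an unadjusted p under 0.05 the counts were 1347 without and 2578 with the block. The groups did not overlap for 2039 probe sets, or 19.8%, where chance gives 10% for exchangeable samples, which samples paired by their number are not. The count of 35 fell to 20 without day 10 replicate 1, to 16 without day 10 replicate 3, and to 19 without any 1 of the 3 day 40 samples; without day 10 replicate 3 the count of at least 2-fold changes was 16. It was 17 without both samples of number 2, which stand apart.

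Among genes higher at 40 days, *Sirt4*, which encodes a mitochondrial sirtuin, rose 13.7-fold, from 9.07 ± 0.21 at 10 days to 12.84 ± 0.12 at 40 days (mean log2 ± SD, n = 3 each; limma adjusted p = 0.000477). The largest rises were those of *CG11353*, by 4.88 ± 0.39 (log2 difference ± SE), and *CG14219*, by 4.47 ± 0.23. Both had a mean under 4 at 10 days, near background, so the size of their change depends on the background correction. *CG7408* rose by 2.81 ± 0.13, from a 10-day mean of 4.18 whose SD of 0.0024 is as flat as background, so the same limit holds for it. *GstD5*, a Delta class glutathione S-transferase, rose by 1.99 ± 0.18, from 5.24 ± 0.30 to 7.23 ± 0.22. *CG6912*, *CG14456*, *CG17944* and *CG32437* rose by 1.78, 1.44, 1.40 and 1.35. *Rnf11*, which encodes a RING finger protein, rose by 1.62 on 1 probe set, while its brighter probe set gave 0.79 (adjusted p = 0.122, and 0.0355 with the block). The 2 probe sets of *CG17944* both rose, by 1.40 and 1.30. Limma adjusted p of these 10 genes lay between 0.000477 and 0.0149, and for each gene all 3 samples of 40 days lay above all 3 of 10 days. With 1 sample left out, *CG11353* lost its call without day 10 replicate 1 or 3 or day 40 replicate 2 or 3 (adjusted p up to 0.0962), and *CG6912* without day 10 replicate 1 or 3 (up to 0.0910). *CG14456* lost it without day 10 replicate 2 or any day 40 sample (up to 0.0900). *GstD5* kept it only without day 10 replicate 1 and *CG32437* only without day 40 replicate 1, with adjusted p up to 0.122 and 0.0853 otherwise. Without both samples of number 2 these 5 genes lost their call, and so did *Rnf11* (0.0766) and *CG17944* (0.118).

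Among genes lower at 40 days, *CG7900* fell by 5.05 on the log2 scale, from 8.29 ± 0.14 to 3.24 ± 0.16 (mean log2 ± SD, n = 3 each; limma adjusted p = 0.000102). The carboxylesterase gene *alpha-Est2* fell as well, with a log2 difference of -5.04 ± 0.27 (SE), as did *CG18233*, at -4.42 ± 0.40, and *Oatp58Db*, which encodes an organic anion transporter, at -3.79 ± 0.14. All 4 had a mean under 4 at 40 days, near background. *CG40298*, *CG14879* and the beta-galactosidase gene *Ect3* had differences of -1.96, -1.93 and -1.73, and *CG31406* and *CG3568* of -1.52 and -1.33. *Cbp80*, the large subunit of the nuclear cap binding complex, fell by 1.68 on 1 probe set, while its dimmer probe set gave 0.03 (adjusted p = 0.938). The other, on average brighter probe set of *CG31406* gave -0.22 (adjusted p = 0.352). Limma adjusted p of these 10 genes lay between 0.000102 and 0.0188, and for each gene all 3 samples of 40 days lay below all 3 of 10 days. With 1 sample left out, *CG18233* lost its call without day 10 replicate 3 or any day 40 sample (adjusted p up to 0.122), and *Cbp80* without day 10 replicate 3 (0.0504). *CG40298* kept it only without day 10 replicate 2 (up to 0.0994 otherwise), and *Ect3* lost it whichever of the 6 samples was left out (0.0505 to 0.122). Without both samples of number 2, *Ect3* (0.194), *Cbp80* (0.0627), *CG31406* (0.114) and *CG3568* (0.0730) lost their call.

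**Figure D2:**
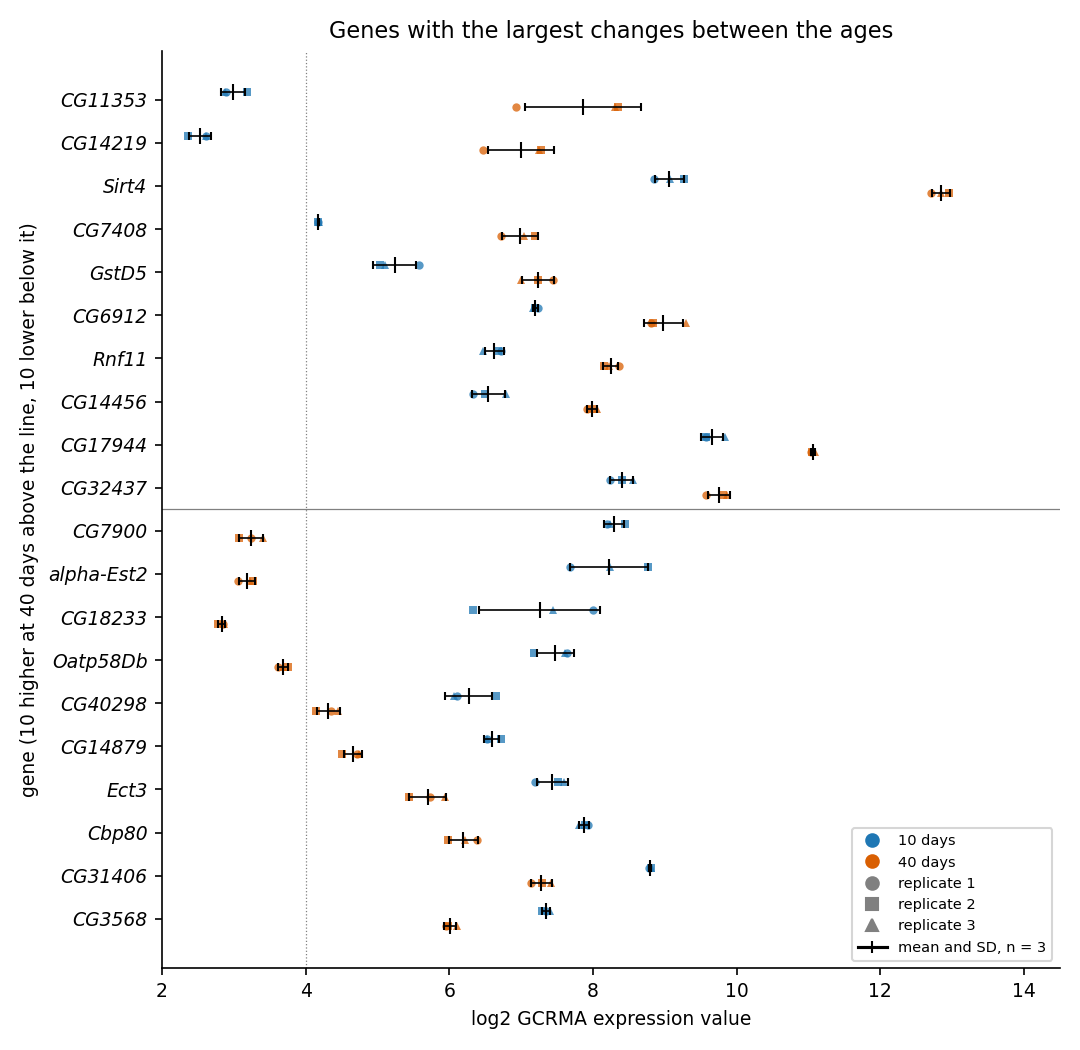
The 10 genes with the largest rise and the 10 with the largest fall between 10 and 40 days, among those called without the block. The x axis gives the log2 GCRMA expression value, coloured symbols are single samples, black bars are the mean and SD of 3 samples, and the dotted line marks the filter level of 4. In every gene shown the 2 ages do not overlap, as for *Sirt4* at 9.07 and 12.84.

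The muscle list was higher at 40 days by the list test and 3 other lists were lower, all by small amounts and none with an estimated correlation. The muscle markers, 24 genes, had a median log2 difference of 0.16, with 17 genes above and 7 below 0 (camera adjusted p = 0.00762, but adjusted p = 0.798 with an estimated correlation). Most lists shared this 0.798, and many shared 0.703 with the block as well, so these values do not tell lists apart. Before adjustment, camera with an estimated correlation gave p = 0.0937 for the muscle list. For the 3 lower lists it gave p from 0.211 to 0.446. Single members did not pass the test over all probe sets, and 5 did when adjusted over the list alone. The actin gene *Act87E* gave 0.38 ± 0.05, *TpnC73F*, a troponin C gene, 0.60 ± 0.15, *sls*, which encodes a titin-like protein, 0.38 ± 0.10 and *Mlp84B* 0.30 ± 0.08 (log2 ± SE; adjusted p = 0.0655, 0.247, 0.260 and 0.263). With the block 2 members passed, *Act87E* (adjusted p = 0.0366) and *TpnC73F* (0.0416), and 15 of 24 passed when adjusted over the list alone, 13 higher and 2 lower. The list's adjusted p stayed at or under 0.0421 with any 1 sample left out, and ran from 0.00151 to 0.798 over 18 alternatives. In all, 4 of the 31 lists tested passed, a count that was 6 with the block, 3 of them shared. It was 0 with an estimated correlation and 0 by fry's directional test without the block. It was 9 without day 10 replicate 1 and 8 without day 40 replicate 2. By fry's directional test with the block, run outside the alternatives listed, the muscle list gave adjusted p = 0.0309. The 3 lower lists gave adjusted p from 0.300 to 0.545 by that test.

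Nuclear genes of oxidative phosphorylation were lower as a list, with a median of -0.05 over 55 genes and 45 of them below 0 (camera adjusted p = 0.00762, and 0.00445 with the block). The call ended at adjusted p = 0.798 with an estimated correlation, and at 0.822 with the block as well. None of them passed the test singly, nor when adjusted over the list alone, and *ND-20*, *SdhB*, *COX7A* and *SdhC*, subunits of complexes I, II and IV, gave -0.17, -0.31, -0.16 and -0.16 (limma adjusted p between 0.345 and 0.403). Mitochondrial ribosomal protein genes were lower as a list too, with a median of -0.05 over 71 genes and 47 below 0 (camera adjusted p = 0.0290). The call ended with the block (0.0525) and at adjusted p = 0.798 with an estimated correlation. None of these passed singly, nor when adjusted over the list alone, and *mRpL2* gave -0.25 and *mRpS5* -0.29 (limma adjusted p = 0.310 and 0.312). Over 18 alternatives the adjusted p ran from 1.85e-06 to 0.822 for the first and from 0.00294 to 0.823 for the second. After quantile normalization the oxidative phosphorylation list gave 0.0959. Without day 10 replicate 2, their adjusted p was 0.335 and 0.276. The mitochondrial ribosomal list was also lost without day 10 replicate 3 (0.0591), day 40 replicate 2 (0.182) or day 40 replicate 3 (0.0778). Without both samples of number 2 the 2 lists gave 0.381 and 0.480.

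Glutathione S-transferases, enzymes of detoxification, were lower as a list while 1 member rose. The 30 genes had a median of -0.14, with 24 below 0 (camera adjusted p = 0.0290, and 0.00445 with the block). The call ended at adjusted p = 0.798 with an estimated correlation, and at 0.703 with the block as well. *GstD5* rose, as given above, and no member fell past the test over all probe sets. Adjusted over the list alone, *GstD5* was higher and 2 genes were lower, *GstD10* at -0.84 ± 0.11 and *GstZ1* at -1.77 ± 0.40. With the block 3 members fell: *GstD10* (limma adjusted p = 0.0233), *GstZ1* (0.0373) and *GstD7* (0.0136), which differed by -1.27. The list had adjusted p = 0.332 without day 10 replicate 2, 0.0520 without day 40 replicate 3, 0.0556 with a filter at 6 and 0.236 without both samples of number 2. Its 18 alternatives ran from 0.00370 to 0.798.

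Male-specific transcripts, bright in all samples, had a median difference of 0.09 over 26 genes, with 20 of them above 0 (camera adjusted p = 0.0729; 0.0355 with the block; 0.798 with an estimated correlation). *dj*, a sperm protein gene, fell by 1.18 ± 0.07 and was 1 of the 6 members below 0, from 9.51 ± 0.09 to 8.32 ± 0.04 (n = 3 each; limma adjusted p = 0.00347). The spermatid genes *Mst84Db*, *Mst84Dd* and *betaTub85D* gave 0.27, 0.25 and 0.20 (adjusted p = 0.209, 0.256 and 0.316). Without day 10 replicate 2 the list's direction turned (adjusted p = 0.914), and it passed without day 10 replicate 1 (0.00641), day 10 replicate 3 (0.0382) or day 40 replicate 2 (0.0458). After quantile normalization it passed too (0.0485).

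The 62 cytochrome P450 genes bright enough to be tested, of 79 with a probe set, had a median of -0.16. The 16 cuticle protein genes tested, of 105 with a probe set, had one of -0.27. Both gave camera adjusted p = 0.0555, which passed with the block at 0.00591 and 0.0494, and both gave adjusted p = 0.703 with the block and an estimated correlation. The P450 list also passed without day 10 replicate 1 (0.00636), day 40 replicate 2 (0.0458) or day 40 replicate 3 (0.0102), and the cuticle list without day 40 replicate 3 (0.0112). Both passed with arrays centred on their medians (0.0482) or quantile normalized (0.0485), and the cuticle list with a filter at 6 (0.0365). Over 18 alternatives the P450 list ran from 0.00591 to 0.800 and the cuticle list from 0.0112 to 0.798. With the block 4 P450 genes passed, *Cyp6d2* higher by 1.78 and *Cyp12c1*, *Cyp6a18* and *Cyp4d21* lower, by -0.72, -0.86 and -0.99 (limma adjusted p between 0.0253 and 0.0434).

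Antimicrobial peptides, heat shock proteins and the other lists did not pass. Including the 3 lists above, 27 of the 31 lists tested had camera adjusted p between 0.0555 and 0.901 without the block, and 25 of them held no called member. With the block, 17 of the 27 held no called member and 10 held at least 1. *Sirt4* was the only called member, with or without the block, of the list of sirtuins, histone modifiers and heterochromatin genes, which had a median of 0.06 over 20 genes (adjusted p = 0.104). Antimicrobial and immune peptides had a median of -0.06 over 7 genes (adjusted p = 0.678), with *Drs* at 0.20 and *Drsl5* at -0.24 (limma adjusted p = 0.599 and 0.661). Of this list 14 genes had a probe set, and those not tested lay under the filter. Heat shock proteins and chaperones had one of 0.02 over 21 genes (0.475), and *Hsc70-2* gave 0.35 (limma adjusted p = 0.195). Synaptic and neuronal genes gave 0.04 over 39 genes (0.231), with the adenylyl cyclase gene *rut* at 1.63 ± 0.23 (limma adjusted p = 0.0774, and 0.0432 with the block). Gut enzymes gave 0.01 over 34 genes and fat body markers -0.10 over 13, both at adjusted p = 0.475. Glia markers gave -0.09 over 18 genes (0.0555), with *e* at -0.72 and *GLaz* at -0.59 (limma adjusted p = 0.108 and 0.144), and both were lower when adjusted over the list alone. The glia list passed with arrays centred on their medians and without day 10 replicate 3, day 40 replicate 1 or day 40 replicate 3, but had adjusted p = 0.122 with the block and adjusted p = 0.798 with an estimated correlation. In 8 lists, gut enzymes among them, the median or the mean had the other sign than the test. A difference that missed the threshold with 3 samples per age is not shown to be absent.

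**Figure D3:**
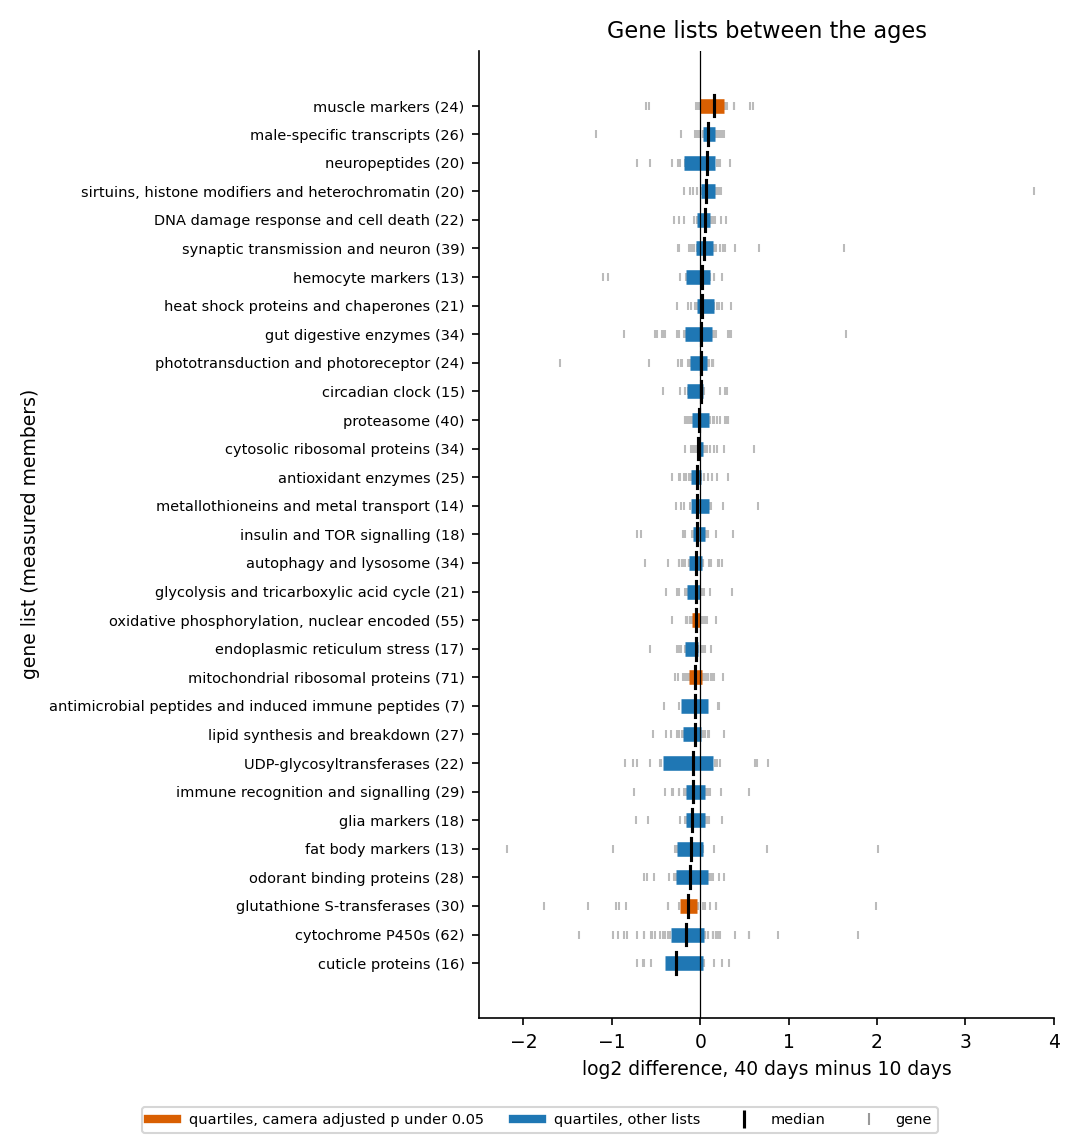
Log2 differences, 40 days minus 10 days, of the genes in the 31 lists tested. Grey ticks are genes, coloured bars span the quartiles, black lines are the medians, and orange marks the 4 lists with camera adjusted p under 0.05. The medians lie between -0.27 for cuticle proteins and 0.16 for muscle markers.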

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

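The fits without both samples of number 2, and the fit with a block and an estimated correlation, were chosen after the data were seen. The count of changed probe sets, 35, was 198 with a replicate block (64 higher, 134 lower), 21 with a filter at 6, 14 by a plain t statistic and 17 without both samples of number 2. The block kept all 35, the filter at 6 shared 21 with them, the plain statistic 10 and the fit without number 2 shared 11. Changes of at least 2-fold, 28, came to 62 with the block, 18 with the filter at 6 and 17 without number 2. With 1 sample left out the counts ran from 16 to 32 and from 16 to 28, with fewer samples in the fit. With no filter 27 probe sets were called, 22 of them shared. With median centring, without a trend and with the robust fit the count was 35 and all were shared; with quantile normalization or values floored at 4 it was 35 with 34 shared, and with array weights 38 with 34 shared.

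The share of the spread between the ages, 29.8%, was 48.9% without number 2, and 30.1% to 40.2% with 1 sample left out. The count of lists past the threshold, 4, was 6 with the block, 7 with median centring and 9 with fry's mixed test. It was 0 with fry's directional test without a block, 0 with an estimated correlation, with or without a block, and 4 to 9 with 1 sample left out. Of the lists of other tissues and males, 1 passed, and 2 did with median centring, quantile normalization or a block. The count was 3 with fry's mixed test, 0 with an estimated correlation or with fry's directional test without a block, and 1 to 3 with 1 sample left out. The male-specific list reversed without day 10 replicate 2, at an adjusted p of 0.914 in a range of 0.00641 to 0.914. The cause of these moves was not tested beyond the smaller number of samples or probe sets.

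The 20 genes named for the largest changes among the calls without the block kept their direction in every fit run on them. All 20 kept their call with the block, array weights, quantile normalization, median centring, no trend and the robust fit; 11 lost it without number 2. With no filter 7 lost it: *CG11353* (0.0559), *GstD5* (0.0779), *CG14456* (0.0642), *CG32437* (0.0544), *CG18233* (0.0779), *CG40298* (0.0771) and *Ect3* (0.0895). The filter at 6 tests 11 of them, and all 11 kept it. With 1 sample left out, 11 of the 20 kept it in all 6 fits. Camera takes no robust fit, so the lists have no value for it. For 6 of the 20 genes 1 age lies under a log2 of 4, where signal over background limits the size of the change.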

Other observations

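The tests of marker levels, of neighbouring genes and of ranges between replicate numbers were chosen only after the result was seen. Members of several lists passed with the replicate block alone, and they were picked after their values were seen. The prophenoloxidase genes *PPO2* and *PPO1*, of the hemocyte list, differed by -1.10 and -1.04 (limma adjusted p = 0.0314 and 0.0367 with the block). The larval serum protein gene *Lsp2*, of the fat body list, differed by -2.19 (0.0317), a size limited by 40-day values of 2.95 and 2.96 in 2 samples, near background. In the phototransduction and photoreceptor list, *laza* and *ninaD* differed by -0.58 and -1.58 (0.0379 and 0.0250). *Syt7*, of the neuron list, was higher by 0.67 (0.0468), and of the gut list *Jon99Fi* was higher by 1.65 (0.0446), while *Jon74E* and *mag* differed by -0.51 and -0.41 (0.0372 and 0.0468). *Idh3g*, of the glycolysis and tricarboxylic acid cycle list, differed by -0.38 (0.0372), and *Ugt35A1* and *Ugt304A1*, of the UDP-glycosyltransferases, by -0.76 and -0.85 (0.0253 and 0.0384). In the muscle list, *fln* and *TpnC4*, both of flight muscle, differed by -0.58 and -0.61, the furthest of 7 members below 0, while the flight muscle actin gene *Act88F* gave 0.56 (0.0141, 0.0315 and 0.0216 when adjusted over the list alone with the block).

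Male reproductive genes, at a median log2 of 14.04, and gut genes, at 11.25, were bright in samples labelled female heads. A high background common to all probe sets is argued against, since 22 of 26 genes of the male list, but 1 of 26 of the ovary list, lay in the top 10% of probe sets. Of these lists 0 and 1 genes are in another list. These levels restate the pattern and do not speak to cross-hybridisation of the male probe sets, which stays open. The yolk protein genes *Yp1*, *Yp2* and *Yp3*, made in female fat body, had levels of 7.29, 3.61 and 8.86, with a median of 7.29 and 10.16 the highest value on any array, while female heads as the main source with male tissue mixed in predicted all of them in the top 10% of probe sets, above about 11.5. That prediction was missed, but no female head of known level was measured beside them, so this reading is not excluded. Whole males under a female head label, or a value table of other samples, stay open too, since the lowest array median of the male list, 13.9, restates the pattern and gives them no support of its own; no biological explanation was tested.

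Few genes passed the test between the ages without the block, some of them with large differences, such as 13.7-fold for *Sirt4*. The 31 single genes called made 23 pairs that lay 6 to 100 tested genes apart, where random sets gave a median of 9 and a 95th percentile of 15 (p = 9e-04, one-sided permutation test), as between *dj* and *CG7900*, 88 genes apart, or *rb* and *Sirt4*, 60 apart. The 168 placed genes called with the block made 372 such pairs against a random median of 290 (permutation p = 1e-04, the smallest that 10000 draws can give). Inherited differences between the cohorts collected at each age may give this excess of pairs. The random sets were not matched on genes that move together, so the excess does not tell this from other causes that move neighbouring genes together. Tandem gene families are argued against as the whole cause, since these 23 pairs leave out any up to 5 genes apart, of which there was 1 (permutation p = 0.408). Age itself stays open as untested, and the 10 splits of the 6 samples are too few for a share under 0.05: the real split gave 35 calls and the highest of the others 1, or 0 among those that also part all 3 pairs.

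Samples with the same replicate number deviated together in both ages. The gut list had a median range of 0.935 log2 between the numbers, where random lists of its size and level gave a median of 0.198 and a 95th percentile of 0.256. The fat body list gave 0.73 and the antimicrobial peptide list 0.88, while muscle markers gave 0.20, the male-specific list 0.18, neuronal genes 0.22, glia markers 0.23 and photoreceptor genes 0.14, all within or below the random range. A difference in gut content between samples could give this. Of the 31 lists, 10 lay above 95% of random lists and 6 below 5% of them. Random lists draw genes singly, so they understate the spread of lists whose genes move together. The ranges carry no sign, however, and gut genes moved both ways. At 10 and 40 days *Mal-A7* was at 13.72 and 13.58 in number 2 against 11.58 and 11.73 in number 1. *Jon65Ai* was at 9.15 and 8.34 against 11.25 and 11.34. The male-specific median hides accessory gland genes lowest in number 2 at both ages, such as *Acp76A* (12.50 against 14.88 and 14.67 at 10 days). A difference in tissue makeup thus stays open, though the muscle, neuronal, glia and photoreceptor medians show none. A shared collection, labelling or scan day cannot be told apart from these, since the labels give no batch, and the lowest correlation between samples of the same number was 0.353.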
